A study of Homo sapiens with 6 samples.

How the data were processed

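Gene expression and splicing were measured by polyA-selected, stranded RNA sequencing in 6 libraries of U2OS cells, a human osteosarcoma line, carrying a doxycycline-inducible TDP-43 with a mutated nuclear localization signal and a fluorescent Clover tag. TDP-43, encoded by TARDBP, is a nuclear RNA-binding protein that represses the use of many splice sites. Per the labels, cells received 50 nM fibril seeds made from the low-complexity domain of recombinant TDP-43, or storage buffer alone, with a lipid transfection reagent. After 48 hours an image-based cell sorter collected cells with Clover aggregates from the seeded cultures and cells with diffuse Clover signal from the buffer-treated cultures. Each group held 3 libraries from separate transfections, which the series design describes as independent biological replicates, and the labels give all 6 libraries the same batch. Group, fibril exposure and sort gate coincide in this design, so the comparison cannot assign a difference to any of them alone.

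Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.11a and the genome build hg38 were used to make the files. The gene counter, its strand setting, its annotation and the LeafCutter version are not given in the sources used here. The deposited values are whole-number counts in both tables, not normalized: counts per gene, with 36601 rows, and LeafCutter counts of spliced reads per intron, with 153462 introns in 39496 clusters. LeafCutter is a program that groups introns sharing a splice site into clusters. Because every deposited cluster holds several introns, an intron without any alternative is not measured in that table. The gene table gives 10 names to more than 1 row, and these rows were kept apart. Every row carries a gene name. Because strand handling is not stated for the counting, genes overlapping an antisense partner remain uncertain, as do near-identical copies such as HSPA1A and HSPA1B or the AKR1C genes.

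Total gene counts were 42862315, 46863013 and 41528336 in aggregate libraries 1, 2 and 3 and 40279084, 41753429 and 43091428 in diffuse libraries 1, 2 and 3. Total intron counts were 29172738, 32020553 and 28529818 and 25341453, 25578200 and 26907926 in the same order. A single count corresponds to 0.0213 to 0.0248 CPM (counts scaled to a total of 1e6). Replicates of a group differed by more than sampling noise, with a chi-square of 2.59 to 6.34 per degree of freedom, so no library was treated as a copy of another. Read counts carry no molecular identifiers, so binomial intervals (exact Clopper-Pearson, 95%) and limits from a count of 0 (3 counts of the total) cover counting error alone.

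Genes were tested with edgeR 4.0.16 in R 4.3.3: filterByExpr by group, TMM scaling, robust quasi-likelihood fit and F test of aggregates against diffuse, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common biological coefficient of variation was 3.1%. Levels are TMM-scaled CPM. A total of 25 gene lists, among them markers of other cell types, had been written down before the data were examined. They were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, adjusted over the lists; correlation estimated per list and fry served as alternatives. Where a list uses newer symbols than the file, members were matched through Ensembl identifiers to the names of GENCODE 29.

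For splicing, introns with at least 10 counts over the 6 libraries were kept, in clusters with at least 2 such introns and at least 10 counts in every library. Clusters were tested with edgeR diffSpliceDGE, which compares the log change of each intron with that of its cluster, combined per cluster by the Simes method and adjusted over clusters. Percent use is the intron count divided by the cluster count in a library. Intron coordinates were converted to first and last intron base, counted from 1, on hg38. Introns were placed in genes by their splice sites in GENCODE 29, an annotation of the same genome build. Annotated introns held 98.5% of the counts of the tested introns. Of the deposited introns, 95517 are annotated there. The rest pair annotated sites in a new way (14111), use an unannotated acceptor (20157) or donor (16295), or match no annotated site (7382). Here unannotated means absent from GENCODE 29. Among tested clusters, 527 could not be placed in a gene. Exon inclusion was computed as the mean of both flanking introns over that mean plus the skipping intron, among the introns of a named cluster that moved most. Enrichment of a list of TDP-43 splicing targets, written from general knowledge before the data were examined, was tested with a two-sided Fisher exact test over genes with a tested cluster.

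Genes and introns named in the text follow a rule fixed before the data were examined. It takes TARDBP first, then the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM and no overlap between groups. From each list it takes up to 4 changed members with the smallest adjusted p, or where none passed the member with the smallest p, given as values. For splicing it takes the 10 introns with the largest change in percent use, from different clusters with at least 20 counts in every library, and then up to 10 genes of the TDP-43 list with the smallest cluster p, by their intron with the largest change. Not every gene that the rule admits is printed. Features outside the rule are said to have been chosen after their values were seen.

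The procedures were tested on simulated counts drawn from the means and library sizes of these libraries. For the gene comparison (17594 genes), 80.6% of 67 genes changed 1.25-fold were recovered, 100% of 67 changed 1.5-fold and 100% of 66 changed 2-fold, with 8 false calls. For the cluster comparison (34284 clusters), 20.9% of 67 clusters shifted by 5 percentage points were recovered, 38.8% of 67 shifted by 10 points and 84.8% of 66 shifted by 20 points, with 0 false calls, so the cluster test misses many moderate shifts. For the gene lists (17839 genes), the raised list was recovered and 0 of 24 other lists were called. Simulated genes were drawn independently of each other, with the same dispersion for all. False calls among lists of correlated genes were therefore not tested by this simulation. All genes and clusters other than those named were left unchanged, whereas 75.4% of the real genes changed. The behaviour of the tests against such a background was not simulated.

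Alternatives fixed before the data were examined were other size factors or none, other count filters, DESeq2 1.42.0, limma-voom, a non-robust fit, a fold threshold of 1.2, the replicate number as a block, other list and cluster tests, a minimum change of 10 percentage points, and leaving out each library in turn. Alternatives added after seeing the data were a per-library correction for GC content and exonic length (17274 of 17839 tested genes, 96.8%, had both values), removal of TARDBP, and matching of genes on junction counts.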

Results

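The study compared the RNA of U2OS cells in which seeded TDP-43 had formed aggregates with that of cells in which the same tagged, nuclear-import-impaired TDP-43 stayed diffuse. Its title asks for effects of seeding on cytoplasmic aggregation and on the nuclear function of TDP-43. There were 3 libraries of sorted aggregate cells and 3 of sorted diffuse cells, with 40279084 to 46863013 gene counts and 25341453 to 32020553 spliced-read counts per library. Values below are mean ± SD over n = 3 libraries per group unless stated otherwise, and fold changes are aggregates over diffuse. Log-CPM profiles correlated at 0.996 to 0.997 within groups and 0.965 to 0.968 between groups and the leading principal component held 87.9% of the variance.

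TARDBP, the gene of TDP-43 itself (chromosome 1, 11012344 to 11026420, plus strand), was lower in aggregate cells, at 2581 ± 42.5 CPM against 7440 ± 218 CPM in diffuse cells. The log2 fold change was -1.53 (SE 0.04, edgeR quasi-likelihood test, adjusted p = 1.1e-52). TARDBP took 0.255%, 0.26% and 0.261% of all gene counts in the aggregate libraries and 0.73%, 0.731% and 0.761% in the diffuse libraries, with exact 95% Clopper-Pearson intervals of 0.254 to 0.257%, 0.259 to 0.262%, 0.26 to 0.263%, 0.727 to 0.733%, 0.728 to 0.734% and 0.758 to 0.764% in the same order. This count does not separate the endogenous gene from the induced transgene.

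Most of the measured transcriptome differed between the groups. Of 17839 genes tested, 13455 (75.4%) changed, 6741 upward and 6714 downward in aggregate cells. Changes above 2-fold were found for 1191 risen and 1447 fallen genes, and above 4-fold for 286 and 206. The groups did not overlap in 76.2% of the tested genes, where chance alone gives 10% for 3 libraries against 3. Among genes with a mean of at least 5 CPM and no overlap between groups, the largest rises were those of DCDC2C, a doublecortin-domain gene (chromosome 2, 3703592 to 3847411, log2 fold change 5.87, SE 0.11), the long non-coding RNA LINC00520 (5.77), the organic anion transporter SLCO2B1 (5.55), the matrix metalloproteinase MMP3 (5.05), LCAL1 (4.93), LINC01444 (4.86), the aldo-keto reductase AKR1C1 (4.53), AC003092.1 (4.45), AL138828.1 (4.43) and SPP1, which encodes osteopontin (4.37). MMP3 went from 6.52 ± 0.437 to 216 ± 14.8 CPM and SPP1 from 12.5 ± 0.61 to 259 ± 11.1 CPM. By the same limits the largest falls were those of the chemokine CXCL14 (-4.06, SE 0.10), the dopamine receptor DRD1 (-3.74), the laminin subunit LAMA3 (-3.59), the forkhead factor FOXS1 (-3.56), the transcription cofactor LBH (-3.46), the tendon transcription factor SCX (-3.44), LINC01505 (-3.10), the keratin KRT14 (-3.00), the transcriptional coregulator MN1 (-2.94) and the water channel AQP1 (-2.79). LBH fell from 207 ± 8.2 to 18.9 ± 1.5 CPM. Adjusted p for these 20 genes was at most 2.14e-17, the value of CXCL14.

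**Figure D1:**
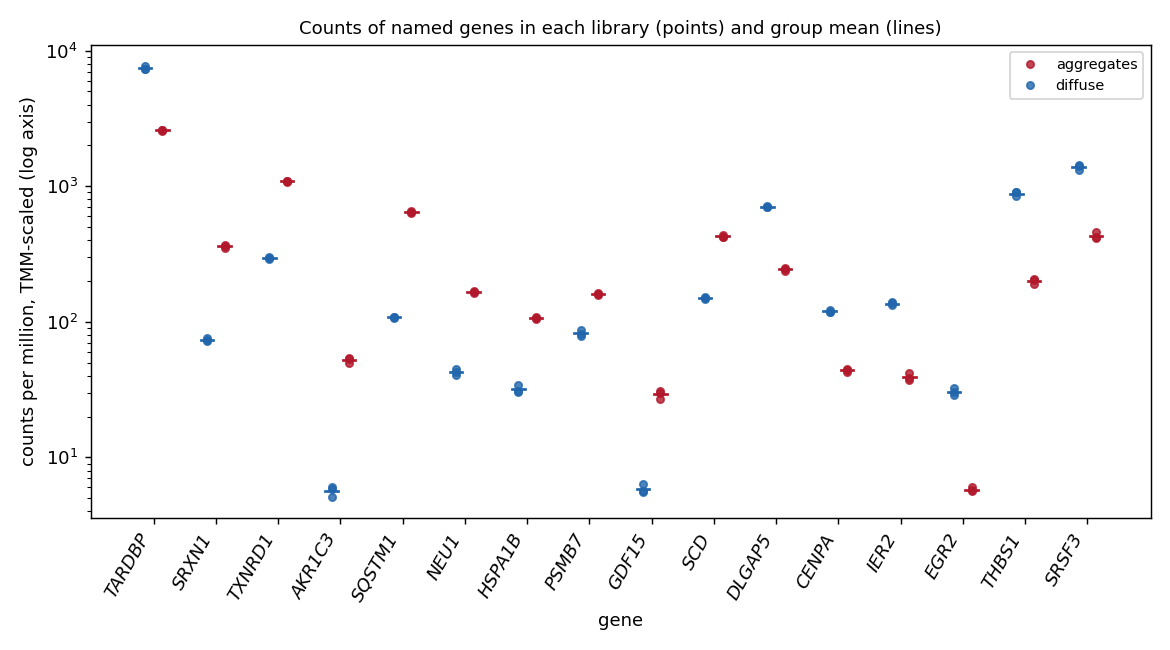
TMM-scaled CPM (log axis) of TARDBP and 15 genes taken from the lists, with a point for each of the 3 aggregate and 3 diffuse libraries and a line at each group mean. The groups do not overlap for any gene shown; TARDBP lies near 2581 CPM in aggregate and 7440 CPM in diffuse libraries.

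Genes of the response to oxidative stress rose together. Of 24 tested targets of the transcription factor NRF2, 23 rose and 1 fell, with a median log2 fold change of 1.31. SRXN1 (chromosome 20, 646615 to 653370), which repairs oxidized peroxiredoxins, rose from 73.9 ± 1.91 to 360.5 ± 7.37 CPM, the thioredoxin reductase TXNRD1 from 297 ± 5.35 to 1089 ± 7.42 CPM, the aldo-keto reductase AKR1C3 from 5.65 ± 0.45 to 52.3 ± 2.53 CPM and OSGIN1 from 15.7 ± 0.971 to 85.8 ± 4.49 CPM. AKR1C3 has near-identical paralogs, and how shared reads were counted is not stated. The list stood apart from other genes by camera with the preset correlation (adjusted p = 1.04e-32), and also with an estimated correlation (adjusted p = 0.0328), the only list of the 25 to do so. Of the 25 lists, which were fixed before the data were examined, 14 passed with the preset correlation.

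**Figure D2:**
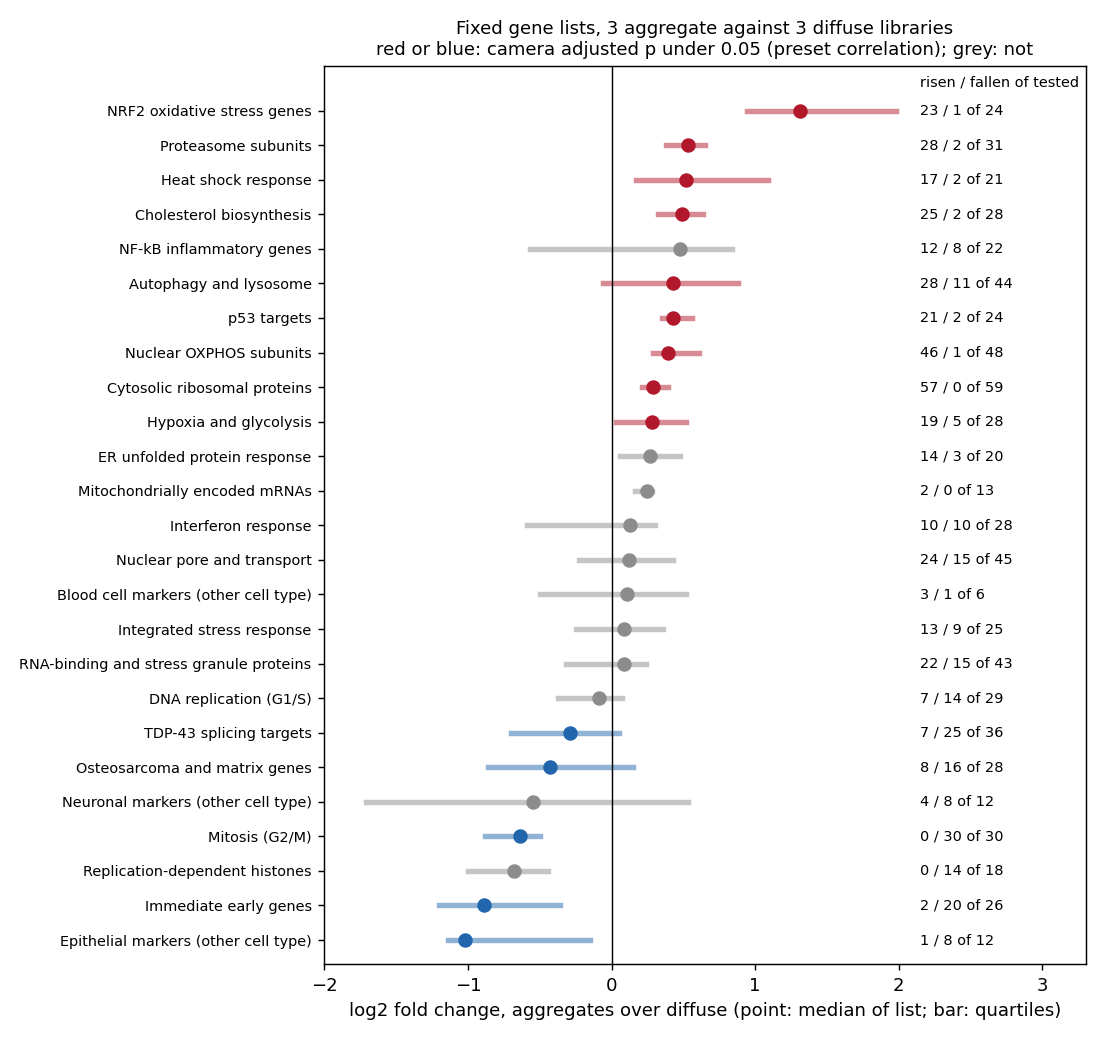
Median (point) and quartiles (bar) of the log2 fold change, aggregates over diffuse, for the members of each of the 25 lists, with the numbers of risen, fallen and tested members at the right. Red and blue mark lists past the threshold of camera with the preset correlation and grey the others; the NRF2 list has the highest median, 1.31.

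For the proteasome, 28 of 31 subunit genes rose and 2 fell (median 0.53, adjusted p = 5.75e-09, but adjusted p = 0.222 with an estimated correlation), and PSMB7 went from 82.7 ± 4.19 to 160.3 ± 2.55 CPM. For autophagy and lysosome genes, 28 of 44 rose and 11 fell (median 0.43, adjusted p = 1.54e-08, and adjusted p = 0.178 with an estimated correlation). The selective autophagy receptor SQSTM1 (chromosome 5, 179806398 to 179838078) rose from 108 ± 1.62 to 648 ± 10.7 CPM (log2 fold change 2.59, SE 0.04, adjusted p = 2.78e-75). The lysosomal sialidase NEU1 rose from 42.7 ± 2.14 to 166 ± 3.07 CPM and the lysosomal membrane protein gene LAMP1 from 346 ± 7.6 to 795 ± 7.46 CPM. For the heat shock response, 17 of 21 genes rose and 2 fell (median 0.52, adjusted p = 7.36e-08, and adjusted p = 0.185 with an estimated correlation). The inducible chaperone HSPA1B went from 31.8 ± 2.25 to 107 ± 1.9 CPM, the small heat shock protein gene CRYAB from 339.7 ± 14.7 to 739.9 ± 25.8 CPM and the mitochondrial chaperonin HSPD1 from 591 ± 16.9 to 1264 ± 40.5 CPM.

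Targets of p53 rose in 21 of 24 cases and fell in 2 (median 0.43, adjusted p = 9.61e-06, and adjusted p = 0.178 with an estimated correlation), among them the stress cytokine GDF15, from 5.84 ± 0.433 to 29.2 ± 1.84 CPM, and the cell cycle inhibitor CDKN1A, from 199 ± 8.58 to 417 ± 19.2 CPM. Adjusted over the list alone, 22 p53 targets rose. Of 28 genes of cholesterol and fatty acid synthesis, 25 rose and 2 fell (median 0.49, adjusted p = 4.12e-08, and adjusted p = 0.185 with an estimated correlation). The stearoyl-CoA desaturase SCD rose from 149 ± 2.96 to 427 ± 8.33 CPM, and DHCR7, an enzyme of cholesterol synthesis, from 36.9 ± 1.19 to 101.9 ± 2.37 CPM. Nuclear-encoded respiratory chain subunits rose in 46 of 48 cases and fell in 1 (median 0.39, adjusted p = 4.85e-09, and adjusted p = 0.227 with an estimated correlation), and ribosomal protein genes rose in 57 of 59 cases (median 0.29, adjusted p = 6.43e-06, and adjusted p = 0.495 with an estimated correlation; with GC and length correction median 0.11, adjusted p = 0.0439). Examples are ATP5MC3, from 82.7 ± 0.861 to 158 ± 1.67 CPM, and RPS24, from 671 ± 16.6 to 1005 ± 22.9 CPM. For hypoxia and glycolysis genes, 19 of 28 rose and 5 fell (median 0.28, adjusted p = 0.0096, and adjusted p = 0.481 with an estimated correlation; with GC and length correction median 0.18, adjusted p = 0.0128), including the hexokinase HK2, from 50.7 ± 3.2 to 135 ± 4.96 CPM.

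Of 13 mitochondrially encoded mRNAs, 2 rose and 11 did not pass (1 rose adjusted over the list alone), and the list did not pass (median 0.25, adjusted p = 0.425, and median 0.04 with GC and length correction). These genes took 3.45%, 3.3% and 3.48% of counts in the aggregate libraries and 2.54%, 3.37% and 2.53% in the diffuse libraries, diffuse replicate 2 lying with the aggregate libraries. Without that library the list passed (median 0.39, adjusted p = 0.00077). MT-CO1 had 7701 ± 140 against 5801 ± 970 CPM (adjusted p = 0.037), a call that was lost without aggregates replicate 1 (adjusted p = 0.114) or 3 (0.128), without a filter on low counts (0.0706), against a fold of 1.2 (0.139) and with GC and length correction (0.377). MT-ND3 rose from 750.4 ± 60.2 to 859 ± 30.6 CPM, which did not pass against a fold of 1.2 (adjusted p = 0.989).

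All 30 mitosis genes fell (median -0.64, adjusted p = 2.6e-14, but adjusted p = 0.178 with an estimated correlation). The spindle gene DLGAP5 fell from 706 ± 9.64 to 243 ± 7.57 CPM, the centromeric histone gene CENPA from 119.5 ± 2.77 to 43.7 ± 0.902 CPM and the checkpoint kinase gene BUB1B from 153 ± 5.32 to 69.6 ± 2.04 CPM. Of 29 DNA replication genes, 14 fell and 7 rose, and the list did not pass (median -0.09, adjusted p = 0.116); CDC6, a replication licensing factor, fell from 241 ± 5.1 to 109.6 ± 2.49 CPM. Of 18 replication-dependent histone genes, 14 fell and 0 rose, without the list passing (median -0.68, adjusted p = 0.149); HIST1H2BJ went from 9.56 ± 0.408 to 3.88 ± 0.209 CPM. With GC and length correction both lists passed (adjusted p = 0.0296 and 0.0373). Most histone mRNAs lack a polyA tail, so these libraries sample them incompletely.

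Immediate early genes, which respond rapidly to growth factors and stress, fell in 20 of 26 cases and rose in 2 (median -0.89, adjusted p = 8.96e-10, but adjusted p = 0.0635 with an estimated correlation); 21 fell adjusted over the list alone. IER2 fell from 136 ± 3.56 to 39.2 ± 2.66 CPM, EGR2 from 30.6 ± 1.71 to 5.79 ± 0.195 CPM and FOS from 366 ± 3.59 to 136 ± 8.84 CPM. Osteosarcoma and extracellular matrix genes fell in 16 of 28 cases and rose in 8 (median -0.43, adjusted p = 0.00486, and adjusted p = 0.481 with an estimated correlation). The matricellular gene THBS1 fell from 883 ± 35.1 to 200.3 ± 9.17 CPM, the protease inhibitor TIMP3 from 189.8 ± 7.61 to 52.4 ± 1.33 CPM and the collagen gene COL3A1 from 174 ± 3.47 to 55.3 ± 3.2 CPM, while SPP1 of the same list was among the largest rises named above. With GC and length correction the median of this list was -0.27 (adjusted p = 0.0322). For the lists where no other count is given, the counts adjusted over the list alone equalled those over all genes.

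Several stress and RNA-processing lists had members moving both ways and did not pass. In the integrated stress response 13 of 25 genes rose and 9 fell (median 0.09, adjusted p = 0.249): the pseudokinase gene TRIB3 rose from 91.3 ± 4.55 to 177 ± 3.06 CPM while ATF3 fell from 111 ± 3.45 to 68.7 ± 3.41 CPM. In the unfolded protein response of the endoplasmic reticulum 14 of 20 rose and 3 fell (median 0.27, adjusted p = 0.066), with EDEM1 rising by 1.09 and DNAJB9 falling by 1.22 on the log2 scale. That list passed without aggregates replicate 2 (adjusted p = 0.0107) or diffuse replicate 1 (0.0241). Of 22 inflammatory genes of the NF-kB list 12 rose and 8 fell (median 0.48, adjusted p = 0.0902). SOD2 rose by 1.52 and IER3 fell by 1.36, and the list passed without aggregates replicate 2 (0.0444), diffuse replicate 2 (0.027) or diffuse replicate 3 (0.0219). With the replicate number as a block the NF-kB list passed as well (camera adjusted p = 0.0258). Of 28 interferon response genes 10 rose and 10 fell (adjusted p = 0.839); IFIT1 fell from 7.52 ± 0.343 to 2.5 ± 0.27 CPM. The median of that list was 0.13 and its mean -0.06, so they differ in sign. Of 45 nuclear pore and transport genes 24 rose and 15 fell (median 0.12, adjusted p = 0.261, but 0.00982 with GC and length correction), with NUP50 falling from 234 ± 3.47 to 125 ± 3.37 CPM. Of 43 genes of RNA-binding and stress granule proteins 22 rose and 15 fell (median 0.09, mean -0.05, camera direction downward, adjusted p = 0.839); the direction turned upward among genes of at least 5 CPM, without aggregates replicate 2 and with GC and length correction, without passing (adjusted p = 0.939, 0.848 and 0.355). The splicing factor SRSF3 fell from 1385 ± 53.8 to 433 ± 25.1 CPM and the stress granule protein gene G3BP2 from 335 ± 4.45 to 194 ± 5.03 CPM.

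Markers of other cell types moved in both directions. Epithelial markers fell in 8 of 12 cases and rose in 1 (median -1.02, adjusted p = 0.00354, and adjusted p = 0.178 with an estimated correlation). The falls included the keratins KRT14, named above, KRT18, from 328 ± 12 to 149 ± 2.18 CPM, and KRT8, from 360.04 ± 23.9 to 163 ± 0.888 CPM. EPCAM and CDH1 did not pass, at 4.07 ± 0.466 against 4.62 ± 0.0785 CPM and 3.64 ± 0.542 against 3.59 ± 0.181 CPM (chosen after their values were seen). Neuronal markers fell in 8 of 12 cases and rose in 4 (median -0.55, adjusted p = 0.0831, but 0.0405 with GC and length correction). ELAVL2 fell from 88.5 ± 0.383 to 14.4 ± 0.635 CPM and STMN2, also a member of the TDP-43 list, from 2.56 ± 0.33 to 0.206 ± 0.0828 CPM, whereas RBFOX3 rose from 2.79 ± 0.159 to 20.1 ± 1.49 CPM. Of 6 blood cell markers 3 rose and 1 fell (median 0.11, adjusted p = 0.282, the median turning negative without aggregates replicate 1 or 3 or diffuse replicate 3); the lysosomal glycoprotein gene CD68 rose from 2.64 ± 0.312 to 14 ± 1.72 CPM, and CD4, at 0.277 ± 0.0943 against 0.475 ± 0.0896 CPM, lost its call without aggregates replicate 2 (adjusted p = 0.174) or diffuse replicate 1 (0.102) and with DESeq2 (0.15).

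Splicing was compared to ask whether introns controlled by TDP-43 were used differently in aggregate cells. Of 35898 clusters tested, holding 144620 introns, 1802 (5%) changed, in 1583 of 11749 genes with a tested cluster. The percent use of some intron moved by at least 10 points in 501 of the changed clusters and by at least 20 points in 206. Among single introns 888 rose and 2082 fell relative to their cluster. Of 685 changed introns with an unannotated splice site, 272 rose and 413 fell. In 204 of them use rose from under 1% in diffuse cells, by at least 5 points in 63 introns of 52 genes; in the opposite direction 292 fell to under 1% in aggregate cells, 30 of them by at least 5 points. The cluster count depends on the test and on the number of libraries. Leaving out any 1 library gave 1171 to 1318 and a cluster F test 2721.

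In clusters with at least 20 counts in every library, several of the largest changes were losses of an annotated intron to an alternative inside it. In CACNA1C, a calcium channel gene, use of the intron at chromosome 12, 2512985 to 2549942 fell from 79.1 ± 3.55% to 13.97 ± 4.29%, as an annotated 75-nucleotide exon (2547450 to 2547524) went from 11.7 ± 2.24% to 75.7 ± 6.49% inclusion. In EPB41L4A (chromosome 5, minus strand) use of the intron 112266331 to 112275325 fell from 98.6 ± 2.46% to 34.6 ± 8.86%. An unannotated 75-nucleotide exon inside it (112267210 to 112267284) reached 49.1 ± 10% inclusion against 0.725 ± 1.26%. In CEP72, a centrosomal gene on chromosome 5, the intron 647917 to 652987 went from 100% in each diffuse library to 50.8 ± 9.67%, with an unannotated exon (648100 to 648223) at 33 ± 8.85% in aggregate cells. Its flanking introns had 0 of 201 cluster counts in diffuse cells, which allows a share of up to 1.49%. In SHANK1 (chromosome 19, minus strand) use of the intron 50704515 to 50711370 fell from 100% to 45.8 ± 1.05%, and an unannotated acceptor (intron 50708844 to 50711370) took 50.2 ± 2.41% against 0 of 143 counts, which allows up to 2.1%. In PPFIBP1 on chromosome 12, the intron 27676600 to 27679488 fell from 78.3 ± 2.66% to 19.96 ± 3.43% of the cluster. It skips an annotated 33-nucleotide exon (27677064 to 27677096), whose inclusion rose from 10.3 ± 1.79% to 65.1 ± 4.77%. Cluster adjusted p for these 5 genes ran from 3.15e-24 (PPFIBP1) to 6.1e-06 (CACNA1C).

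Other large changes concerned FAM49A, C15orf39, RNF103-CHMP3 and PHF21B. In FAM49A the intron at chromosome 2, 16588130 to 16622938 rose from 18.4 ± 1.6% to 73.0 ± 4.01%. In C15orf39 the intron at chromosome 15, 75208825 to 75210748 fell from 69.4 ± 4.34% to 17.04 ± 3.34%, while an annotated intron with a later donor (75208877 to 75210748) rose from 30.6 ± 4.34% to 83.0 ± 3.34%. In the RNF103-CHMP3 cluster, which covers 2 coding genes, the intron at chromosome 2, 86620470 to 86622660 fell from 93.0 ± 2.01% to 41.9 ± 2.45%. In PHF21B the intron at chromosome 22, 44920491 to 45008544 went from 32.3 ± 8.02% to 80.8 ± 4.4% (cluster adjusted p = 0.013) on 26 to 58 counts per library. That call was lost without aggregates replicate 2 (0.11), diffuse replicate 2 (0.122) or diffuse replicate 3 (0.0733).

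**Figure D3:**
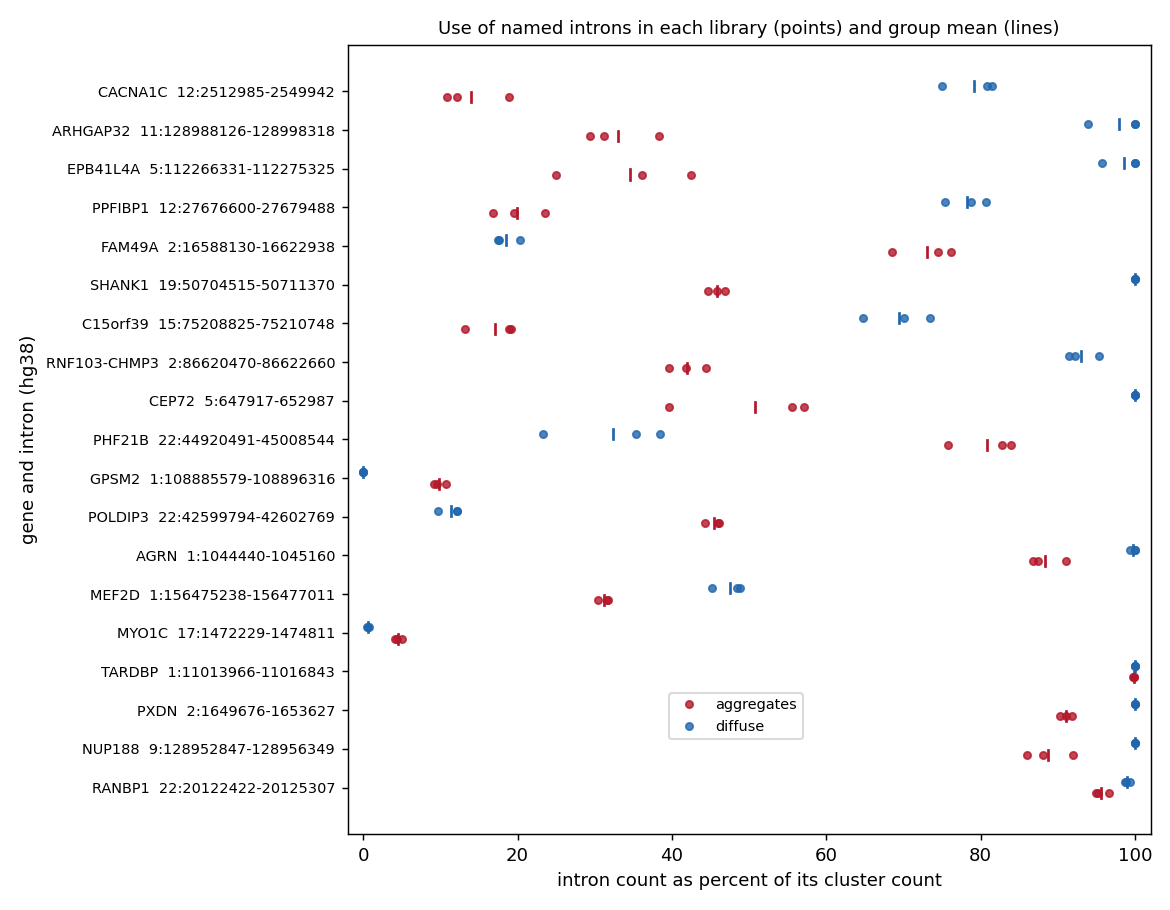
Percent of the cluster count taken by each named intron (gene and hg38 coordinates on the vertical axis), with a point for each of the 3 aggregate and 3 diffuse libraries and a line at each group mean. CACNA1C is the largest change shown, from 79.1% in diffuse to 13.97% in aggregate libraries; the TARDBP intron stays above 99% in both groups.

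Genes of the TDP-43 target list changed splicing far more often than other genes. The groups also differed in TARDBP RNA, at 2581 CPM in aggregate and 7440 CPM in diffuse cells. An effect of that level, from the endogenous gene or the transgene, cannot be told apart from an effect of aggregation here. A changed cluster was found in 23 of 33 list genes with a tested cluster (69.7%) and in 1560 of 11716 other genes (13.3%), an odds ratio of 15 (95% interval 6.84 to 35.3, two-sided Fisher exact test, p = 1.96e-13). The odds ratio was 10.2 among genes matched on the number of tested clusters, and the 11 alternatives ranged from 10.2 to 22.6 with p from 7.15e-17 to 4.01e-10. In ARHGAP32 on chromosome 11, use of the annotated intron 128988126 to 128998318 fell from 98.0 ± 3.53% to 33.0 ± 4.71%, and an unannotated acceptor (intron 128992047 to 128998318) rose from 2.04 ± 3.53% to 67.0 ± 4.71%. In GPSM2, a spindle orientation gene on chromosome 1, an unannotated 115-nucleotide exon (108896317 to 108896431) was included at 12.6 ± 0.955%. Its upstream intron had 0 of 3404 cluster counts in diffuse cells, which allows up to 0.0881% of the cluster, and 9.80 ± 0.853% of the cluster in aggregate cells. In POLDIP3 on chromosome 22, the intron 42599794 to 42602769 rose from 11.4 ± 1.39% to 45.4 ± 1.03% of the cluster. It skips an annotated 87-nucleotide exon (42601970 to 42602056), whose inclusion fell from 79.6 ± 2.25% to 37.5 ± 0.982%. In MEF2D on chromosome 1 inclusion of a 21-nucleotide annotated exon (156476494 to 156476514) rose from 6.68 ± 0.418% to 28.9 ± 2.57%. Unannotated exons also appeared in AGRN (1044892 to 1044987, 5.61 ± 1.12% against 0.0225 ± 0.039%), PXDN (1650800 to 1650886, 4.66 ± 0.422%) and NUP188 (128956141 to 128956174, 6.01 ± 1.69%). The introns of the PXDN and NUP188 exons had no count in diffuse cells, which allows 0.232% and 0.253% of their clusters. Smaller shifts were seen in MYO1C and RANBP1. The MYO1C intron 1472229 to 1474811 rose from 0.631 ± 0.117% to 4.49 ± 0.526%. The main RANBP1 intron went from 99.0 ± 0.385% to 95.6 ± 0.923%, a change that did not pass by itself. Inclusion of an annotated exon inside it (20122580 to 20122697) went from 0.518 ± 0.194% to 2.26 ± 0.482%. The TARDBP cluster changed as well, a call that was lost with limma diffSplice (adjusted p = 0.269). Its intron 11015647 to 11016843 passed, at 0.198 ± 0.00674% in aggregate and 0.0153 ± 0.0135% in diffuse cells (diffSpliceDGE adjusted p = 3.84e-09). The main intron, 11013966 to 11016843, stayed at 99.8 ± 0.00674% against 99.99 ± 0.0135%. The counts of this cluster do not separate the endogenous gene from the transgene.

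In overall level, 25 of 36 tested genes of the TDP-43 list fell and 7 rose, or 8 adjusted over the list alone (median -0.29, camera adjusted p = 0.00224, but adjusted p = 0.178 with an estimated correlation). Besides TARDBP and STMN2, GPSM2 fell from 159 ± 0.862 to 82.5 ± 2.21 CPM, RSF1, a chromatin remodelling gene, from 186 ± 3.26 to 108 ± 5.7 CPM and ARHGAP32 from 80.5 ± 2.31 to 45.7 ± 1 CPM. UNC13A, a synaptic gene of the list chosen here after its values were seen, fell by 0.63 on the log2 scale and had 1 changed cluster of 10 tested (adjusted p = 0.0127, largest change 22.3 points). The introns of that cluster were not examined further. UNC13B and SORT1, chosen in the same way, each had 0 changed clusters of 4 tested (smallest diffSpliceDGE adjusted p = 0.959 and 0.759). STMN2 had 0 tested clusters, so its splicing was not measured here.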

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

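The GC and length correction and the removal of TARDBP were chosen after seeing the data, and the other alternatives named here before. The number of changed genes stayed between 9202 (glmTreat, fold above 1.2) and 14048 (no filter on low counts), against 13455; DESeq2 gave 12307 and library totals alone 13452. With GC and length correction it was 13178, of which 11693 were shared, and 203 genes called both ways had opposite signs. Leaving out 1 library gave 12943 to 13310 genes, 14 to 16 lists, 1171 to 1318 clusters and odds ratios of 15.6 to 22.6 for the TDP-43 list. The 1802 changed clusters became 2721 with the cluster F test, 501 with a minimum change of 10 points and 1171 without diffuse replicate 3, where fewer libraries entered the test. The lists past the threshold went from 14 to 1 with an estimated correlation, which widens the null spread of correlated lists, and to 22 with fry, which does not compare a list with other genes. The RNA-binding list changed direction to upward with a mean of at least 5 CPM (median 0.11), without aggregates replicate 2 and with GC and length correction (0.20), its medians without 1 library lying between 0.065 and 0.092, as did the interferon list, to downward, with fry (median 0.13). Neither list passed in any of these, and the cause was not tested. GC and length correction brought 4 further lists past the threshold: DNA replication (adjusted p = 0.0296), histones (0.0373), nuclear pore (0.00982) and neuronal markers (0.0405). It brought some medians nearer to 0, from 0.29 to 0.11 for ribosomal proteins, 0.25 to 0.04 for mitochondrially encoded mRNAs, 0.28 to 0.18 for hypoxia and -0.43 to -0.27 for matrix genes, and others away from 0, from 0.12 to 0.25 for nuclear pore, -0.09 to -0.17 for DNA replication, 0.09 to 0.18 for the integrated stress response, -0.68 to -0.92 for histones and -0.55 to -0.69 for neuronal markers. The TDP-43 list had adjusted p = 0.0373 in level. Among results for named genes 1954 kept direction and side of the threshold and 10 lost the call: MT-CO1 under 5 alternatives (adjusted p 0.0706 to 0.377), CD4 under 3 (0.102 to 0.174), and MT-ND3 (0.989) and CD8A (0.0962) under glmTreat. Among those for named introns 222 kept both and 4 lost the call, 3 of PHF21B and 1 of TARDBP. With the replicate number as a block there were 13530 genes, 15 lists, 1494 clusters and an odds ratio of 18.4 (Fisher exact test, p = 4.16e-15). The block brought the NF-kB list past the threshold (adjusted p = 0.0258). Deviations of same-numbered libraries correlated at 0.036, 0.083 and 0.06, and 6 of 6 libraries correlated best with their own number, a weak hint from the data and not from the design. The deviations were taken from group means, so the 6 matches are not independent. In simulated data at the depth and number of libraries used here, 20.9% of shifts of 5 points were recovered.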

Other observations

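The families in this and the next paragraph, the test of TARDBP introns and the correction for GC and length were chosen after the data were seen. No p is given for the 12 gene families, taken by name, since a test would use genes chosen for their change, and some members repeat lists given above. Of 10 tested aldo-keto reductases 9 rose and 0 fell (median log2 fold change 2.43), AKR1B10 from 0.17 ± 0.0682 to 4.49 ± 0.216 CPM. Among them 4 are also NRF2 list members, and the other 6, of which 5 rose, had a median of 0.61. Of 8 subunits of the cytosolic chaperonin CCT, which folds actin and tubulin, all 8 rose (median 0.76), CCT2 from 216 ± 4.81 to 382 ± 4.16 CPM. Of 22 genes of the V-ATPase, the proton pump of lysosomes, and its accessory proteins 17 rose and 2 fell (median 0.51, or 0.47 for the 18 outside the lysosome list). Of 13 cathepsins 8 rose and 3 fell (median 0.56), CTSD from 157 ± 7.19 to 312 ± 11.4 CPM, but among the 10 outside that list 5 rose and 3 fell (median 0.17). Of 25 host genes of small nucleolar RNAs 14 rose and 5 fell (median 0.36).

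All 4 ID genes, inhibitors of differentiation factors, fell (median -1.29), ID1 from 281 ± 10.6 to 76.4 ± 1.32 CPM. Of 35 kinesins 27 fell and 5 rose (median -0.44, or -0.36 for the 31 outside the mitosis list), with the mitotic kinesin gene KIF18A going from 248 ± 1.58 to 66.7 ± 1.12 CPM. Of 437 ZNF zinc finger genes 255 fell and 84 rose (median -0.29). Of 16 keratins 9 fell and 5 rose (median -0.70), but of the 11 outside the epithelial list 4 fell and 5 rose (median 0.35). Among tubulins 3 of 17 rose and 11 fell (median -0.29), among metallothioneins 3 of 4 rose and 1 fell (median 0.34) and among dual-specificity phosphatases 7 of 20 rose and 6 fell (median -0.03).

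The 6 libraries can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. The real division gave 13455 changed genes and the highest other 0; it gave 1802 changed clusters and the highest other 4; it gave 23 genes of the TDP-43 list with a changed cluster and the highest other 0. In each of these 3 counts 1 of 10 divisions, the real one, reached the real value. For lists with the preset correlation the real division gave 14 and the highest other 17, and 4 of 10 divisions gave at least 14, so the number of lists called does not set the real division apart. Each other division still leaves 2 libraries of a group on the same side. The NRF2 list passed in 9 of 9 of these divisions. So did the lists of the proteasome, p53 targets, mitosis, cholesterol synthesis, immediate early genes, ribosomal proteins and nuclear-encoded respiratory chain subunits. The heat shock list passed in 8 and the TDP-43 list in 7. Passing at the preset correlation therefore does not set the real division apart for these lists. Because the other divisions keep part of the real contrast, they cannot tell whether a list would pass without a group difference. The real difference also enters the spread within their groups, so their gene and cluster counts do not measure chance either.

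The fall of the TARDBP count does not separate the endogenous gene from the transgene, whose extent the labels do not give. A total of 7 introns in the last part of TARDBP, between 11022178 and 11023314, had 97 counts in aggregate and 100 counts in diffuse libraries. Their log2 ratio was -0.25 (95% exact binomial interval -0.67 to 0.17, counting error only), against -1.53 for the gene. These introns were chosen by their start. Whether each ends in the 3' UTR, and whether any lies in coding sequence, was not checked. The libraries spread widely, with 44, 24 and 29 such counts in aggregate and 26, 33 and 41 in diffuse libraries, or 1.09 ± 0.385 and 1.28 ± 0.249 CPM of all intron counts. The ratio was -0.55 (interval -1.06 to -0.06) without aggregates replicate 1, -0.02 without aggregates replicate 2, -0.38 without diffuse replicate 1 and -0.10 without diffuse replicate 3. An interval from the spread between libraries was -1.20 to 0.66 (t interval on log2 rates), above -1.53 as well. The coding intron at 11013966 to 11016843 went from 1580 ± 35.4 to 470 ± 21 CPM of all intron counts. If the 7 introns come from endogenous RNA alone, these values argue against its fall by the same factor with those introns spliced as often. That condition was not tested. A lower transgene level, a change in the splicing of those introns and the sort gate remain open and untested.

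Introns with an unannotated splice site took 1.14 ± 0.0266% of intron counts in aggregate and 1.32 ± 0.0324% in diffuse libraries, and new pairs of annotated sites 0.297 ± 0.00275% and 0.409 ± 0.00863%. An exact permutation test of 3 against 3 can give no p below 0.1. A few clusters with most of the unannotated counts are argued against, since without the 20 largest the ratio of diffuse to aggregate stayed at 1.16. A different mix of genes cannot be told apart from a change within genes, because equal cluster weights kept 39% of the gap, between the bounds set before. Intron counts per gene count also differed, at 0.684 ± 0.00321 in aggregate and 0.622 ± 0.00852 in diffuse libraries. No biological explanation was tested.

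Coding genes with long introns were lower in aggregate cells. Coding genes without introns were left out of the following groups but not out of the pool for the random lists. The median log2 fold change was 0.14 for 3201 genes whose longest intron was at most 5 kb and 0.04 for 5317 genes at 5 to 20 kb. It was -0.14 for 4499 genes at 20 to 100 kb and -0.23 for 1123 genes above 100 kb. The difference of the last group from 10000 random lists matched on expression was -0.23, and 0 of these lists had a median as low. After correction for GC and length the difference was -0.10 (SD of the lists 0.0204), and 1 of 10000 lists had a median as low. Part of the difference thus went with the correction and part stayed, so a bias of transcript length or GC content cannot be told apart from an effect of the introns as the main cause. No biological explanation was tested.

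Genes with a newly used intron, an unannotated intron that rose from under 1%, may also lose RNA, as a hypothesis. Of 146 such genes 83 fell and 50 rose (median log2 fold change -0.16, against 0.01 for matched lists), and 0.24% of 10000 matched lists had a median as low. Among 50 genes whose intron rose by at least 5 points 36 fell and 12 rose (median -0.45, against 0.02 for matched lists). The median was as low as the hypothesis predicts by this test (0.24%), which does not show that the intron lowered the RNA. The lists were matched on expression and not on intron length, which also went with lower levels above. An effect of intron length thus cannot be told apart from the hypothesis here. Genes with introns that fell to under 1% were not tested in this way.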
